A study of Mus musculus with 16 samples.

How the data were processed

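Gene expression was measured by RNA sequencing in 16 mouse libraries. Per the labels, total RNA was purified on RNeasy Plus columns and amplified with the Ovation RNA-Seq System V2, which primes cDNA synthesis with both random and poly-T primers. Libraries were then made with the Ovation Ultralow kit and sequenced paired-end on a HiSeq instrument. The sample descriptions give a batch for each library. Replicate 1 of D0, D4, D8, D12 and ciNSLC and the SCR029 library are in batch 1. Replicates 2 and 3 and the primary neural progenitors are in batch 2. The submitters' processing notes name TopHat2 2.0.13 for alignment to the mm9 genome, featureCounts from Subread for counting, and edgeR.

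The deposited table holds 37991 genes with Ensembl identifiers and mm9 coordinates. Its raw columns are, per the file headers, non-normalized counts per gene, and these counts were used for every fit. A further deposited column gives CPM (counts of a gene scaled to a common library total) over all genes, and each such column summed to between 999990 and 1000009. The deposited FPKM values equal that CPM divided by the feature length in kilobases. The authors also gave a normalized CPM for 20055 genes, which sums to between 999993 and 1000006 over those genes. In that column 17934 genes are marked as low and 2 genes, the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, as high. The deposited feature length is the summed exon length in bases, another unit that entered no fit. The CPM, FPKM and normalized CPM columns were checked against the counts, and of them only FPKM was used further, in an alternative for the similarity between libraries. No count was found in any library for 9800 genes. Genes without a symbol numbered 415 and took at most 0.151% of the counts of a library.

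Library totals ran from 29.4 to 55.5 M counts (M, mega), so that 3 counts, the number a count of 0 allows at 95% confidence, correspond to 0.054 to 0.102 CPM per library. The 2 mitochondrial rRNA genes took 14.3% to 53% of the counts. Without them the libraries held 14.5 to 34.6 M counts. Intervals and floors given for counts cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

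Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with edgeR's default expression filter on the groups, library sizes were scaled by TMM (trimmed mean of M values), and robust quasi-likelihood fits with group as the only term were tested by the quasi-likelihood F-test. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 14 libraries of D0, D4, D8, D12 and ciNSLC were fitted together, with 17455 genes tested and a common biological coefficient of variation of 0.418. Comparisons with SCR029 and the primary progenitors used all 16 libraries with these 2 coded as one control group, 17636 genes and a coefficient of variation of 0.441. They are different cell sources and not replicates of each other, so the spread of that group includes the difference between them. Levels are given as TMM-scaled CPM, as mean ± SD over libraries, and log2 changes come from the fit with their standard error (SE). Folds against a group without any count are lower bounds against a floor of 3 counts over the whole group. Ratios against a group with 1 to 3 counts carry a 95% counting interval. The labels do not say whether replicates are separate cultures, so the p-values measure a spread between libraries that may be partly technical.

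A total of 32 gene lists with 521 members was fixed, of which 519 were found in the table. Each list was tested with fry from limma 3.58.1, whose directional p asks whether the members move, on balance, one way. It does not compare the list with other genes. These p-values were adjusted over the 32 lists within each comparison. Camera with an estimated correlation between genes, and with a preset one of 0.01, was run beside it. Counts of list members are given over all genes tested and adjusted over the list alone. The groups, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 5 higher and 5 lower genes (3 and 3 between successive treatment days) with the largest log2 change among called genes. Their libraries must not overlap, the higher group must reach 10 CPM, and unnamed or predicted genes are left out. It adds, for each list described, the 4 called members with the lowest p in the list's main direction and up to 2 against it, and a fixed panel of 27 genes.

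The alternatives were DESeq2 size factors in place of TMM, upper-quartile scaling, no expression filter and a filter at 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma voom, a batch term, SCR029 or priNPC as the only control, a block for the replicate number, a fit on only the groups compared, an absolute log2 change of at least 1 beside the p threshold, and each library left out in turn. Similarity between libraries was also computed over the 2000 most variable genes and on the deposited FPKM. Leaving out a D0 or a control library leaves that group with a single library, which is then assumed to vary like the other groups. The overlap with the controls was also counted with ciNSLC and the controls each set against another D0 library, which, like the next fits, was added after the data were seen. These were fits without the mitochondrial rRNA genes, with batch 2 alone, and without 4 doubted libraries (the second D0 and the first D4, D8 and D12 libraries). Batch 2 alone has 1 D0 and 1 control library and 4 residual degrees of freedom, so its counts are no replication. Without the doubted libraries D0 also keeps only its first library. The replicate number follows the batch, and residuals correlated within a batch whether or not the numbers matched. The median correlation of residuals was 0.29, 0.27 and 0.13 for equal numbers 1, 2 and 3, 0.24 for numbers 2 and 3 in batch 2, and -0.26 between batches.

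The tests were also tried on simulated data with the spread of these libraries. Each library was drawn independently there, without a batch effect. Residuals of the real libraries correlate within a batch, so the rates of calls and false calls need not hold for them. There 100 genes each were changed 2-fold and 4-fold, alternately raised and lowered. In a simulated D8 against D4, edgeR called 3% of the 2-fold and 42% of the 4-fold genes with 0 false calls, and DESeq2 called 17% and 69% with 38 false calls. In a simulated D4 against D0, edgeR called 4% and 39% with 2 false calls, and DESeq2 15% and 64% with 42. In a simulated ciNSLC against controls, edgeR called 2% and 22% with 1 false call, and DESeq2 13% and 49% with 48. Tables were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.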

Results

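The 16 libraries follow mouse fibroblasts through a chemical treatment. The starting cells (D0) were tdMEFs, embryonic fibroblasts in which Fsp1-Cre had switched on a tdTomato reporter, so that cells of fibroblast origin stay marked. They were sampled before treatment in 2 libraries and on days 4, 8 and 12 (D4, D8 and D12) in 3 libraries each. The treatment, M9, combines a Wnt activator (a GSK3 inhibitor), a BMP and a TGF-beta receptor inhibitor, a Hedgehog agonist, retinoic acid, an autophagy enhancer, a DNA methylation inhibitor, an LSD1 inhibitor and bFGF, and was given at low oxygen. A further 3 libraries came from ciNSLCs, the neural stem-like cells obtained from treated fibroblasts and grown as lines. The neural controls were SCR029, a mouse neural stem cell line from embryonic cortex, and primary neural progenitors (priNPC), also from embryonic cortex, with 1 library each. Total counts were 44.6 M and 31.2 M (M, mega) at D0, 41, 39.3 and 29.4 M at D4, 45.7, 37.4 and 36.8 M at D8, and 42.1, 31.7 and 34.3 M at D12. The ciNSLC libraries held 55.5, 30.8 and 32.9 M, SCR029 45.1 M and priNPC 36.9 M. The mitochondrial rRNA genes took 52.7%, 49.7% and 33.2% of the counts in replicate 1 of D4, D8 and D12 and 16.5% to 28.4% in the others of these groups. They took 22.6% and 14.3% at D0, 44.3% to 53% in ciNSLC, 47.4% in SCR029 and 32% in priNPC.

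Across genes, the ciNSLC libraries resembled the neural controls more than the cells they came from. The mean Spearman's rho of log2 CPM was 0.939 (SD 0.007, 3 pairs) between ciNSLC and SCR029 and 0.946 (SD 0.006, 3 pairs) between ciNSLC and priNPC, beside 0.933 between the controls themselves (1 pair). Against ciNSLC it was 0.825 for D0, 0.838 for D4, 0.857 for D8 and 0.871 for D12, the last with a range of 0.844 to 0.911 over 9 pairs. By group means treated cells were closer to D0, at 0.922, 0.921 and 0.907 for D4, D8 and D12. The first D12 library lay about as close to both, with 0.917 and 0.893 to the D0 libraries and 0.911, 0.903 and 0.906 to the ciNSLC libraries. Within its own batch it had 0.917 to D0 and 0.911 to ciNSLC. Over the 2000 most variable genes alone, ciNSLC had 0.759 with SCR029, 0.816 with priNPC, 0.377 with D12, 0.229 with D8, 0.072 with D4 and 0.064 with D0. The first principal component held 51.3% of the variance, with ciNSLC and the controls between 143.5 and 183 and every other library between -96.7 and -5.8. The value of -5.8 belongs to the first D12 library, and the others of that day lay at -72.9 and -66. Genes are not independent replicates, so no test is attached to these values.

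**Figure D1:**
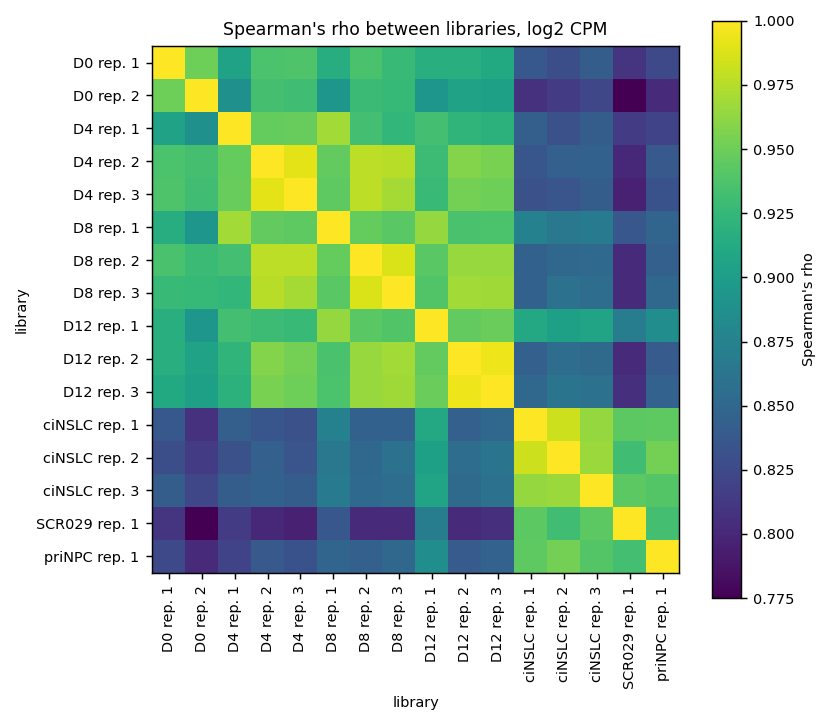
Spearman's rho across tested genes between each pair of the 16 libraries, computed on log2 CPM; both axes list the libraries and colour gives rho. Between ciNSLC and either control rho was 0.931 or more.

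The first question was what 4 days of treatment did to the fibroblasts. Cartilage genes fell. The cartilage protein Comp went from 8.21 ± 2.98 CPM (SD, n = 2) at D0 to 0.0491 ± 0.0643 (n = 3) at D4, the tendon protein Tnmd from 64.4 ± 30.6 to 0.101 ± 0.0895 and the matrix protein Fmod from 177 ± 102 to 0.388 ± 0.174. The actin-binding proteins of smooth muscle Tagln and Cnn1 went from 204 ± 7.75 to 11.7 ± 0.188 and from 78.4 ± 16.4 to 4.46 ± 0.884, and smooth muscle actin Acta2 from 2330 ± 36.7 to 184 ± 17.8. In the other direction, Stra6, the cellular receptor for retinol uptake, rose from 0.719 ± 0.132 to 251 ± 51, and the retinoic acid receptor Rarb from 2.21 ± 0.798 to 104 ± 10.4. The keratin Krt18 rose from 0.0912 ± 0.0184 to 72.9 ± 56.2, and Prom1, a surface protein of many stem cells, from 0.112 ± 0.0478 to 25.2 ± 1.88.

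In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1260 of 17455 genes changed between D4 and D0, 618 higher and 642 lower. Krt18 (ENSMUSG00000023043, chromosome 15, 101858647 to 101862457 in mm9) had a log2 change of 9.58 (SE 1.19, adjusted p = 0.00067). Stra6 (ENSMUSG00000032327, chromosome 9, 57911595 to 58001803) had 8.44 (SE 0.73, adjusted p = 8.6e-05), and Prom1 (ENSMUSG00000029086, chromosome 5, 44384864 to 44493271) had 7.74 (SE 0.51, adjusted p = 1.8e-05). The milk-fat protein Btn1a1 rose from 0.0651 ± 0.0552 to 51.5 ± 14.2 CPM, and the methyltransferase Inmt had a ratio of 767 (95% counting interval 212 to 6330) on 2 counts at D0. The largest decreases were in Wisp2, a secreted matrix-associated protein, at -10.69 (SE 0.95, adjusted p = 9.3e-05), and in Tnmd at -9.24 (SE 0.75, adjusted p = 6e-05). Others were in the tenascin Tnn at -8.96 (SE 0.96, adjusted p = 0.00026), in Fmod at -8.78 (SE 0.84, adjusted p = 0.00016) and in the mesodermal transcription factor Meox1 at -8.37 (SE 0.58, adjusted p = 1.8e-05). The panel genes Col1a1 (8890 ± 92.9 against 1460 ± 1040 CPM, adjusted p = 0.064, or 0.01 with a replicate block, range over alternatives 0.0048 to 0.16) and Sox2 (0.221 ± 0.276 against 0.897 ± 0.567, adjusted p = 0.32) did not pass the test. Within batch 1 alone 99.3% of the 1260 genes had the same sign, and within batch 2 alone 99.8%. These genes were called on the same libraries, so this agreement, here and in later comparisons, is largely set by the selection. Batch 2 holds 1 D0 library, so its counts against D0 rest on a single library there. Batch 2 by itself gave 2626 changed genes, 1067 of them among the 1260. The count was 868 without the first D0 library, 239 higher and 629 lower, so that most calls were then decreases. It was 609 without the second D0 library, 804 without the second D4 library and 827 without the third.

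By gene list, the cartilage and bone markers fell (0 of 10 higher and 5 lower, 0 and 7 adjusted over the list alone, fry adjusted p = 1.4e-08). They kept the call with an estimated correlation (adjusted p = 0.0089). The contractile genes fell (0 higher and 8 lower of 16, 0 and 11 over the list alone, adjusted p = 0.0013, and 0.062 with an estimated correlation). Retinoic acid targets rose (3 higher and 0 lower of 11, 6 and 0 over the list alone, adjusted p = 0.0026, and 0.062 with an estimated correlation). The p53 and cell cycle arrest genes rose (6 and 0 of 14, 9 and 0 over the list alone, adjusted p = 0.0045, and 0.12 with an estimated correlation). Among them were Perp, a p53-induced membrane protein, from 3.8 ± 1.84 to 104 ± 56.4 CPM, and the cell cycle inhibitor locus Cdkn2a from 0.779 ± 0.254 to 5.93 ± 1.78. The integrated stress response genes fell on balance (0 and 2 of 14, 2 and 7 over the list alone, adjusted p = 0.0013, and 0.062 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, from 31.1 ± 10.7 to 3.25 ± 1.45. BMP targets fell (0 and 2 of 12, 0 and 4 over the list alone, adjusted p = 0.0049, and 0.12 with an estimated correlation). The fibroblast matrix and surface genes fell (1 and 9 of 24, 1 and 17 over the list alone, adjusted p = 0.013, and 0.16 with an estimated correlation), including the receptor Pdgfrb from 192 ± 2.67 to 9.65 ± 3.11, though their p was 0.052 without the second D0 library (range over alternatives 9.4e-12 to 0.16). Wnt targets rose (4 and 1 of 12, 5 and 1 over the list alone, adjusted p = 0.0086, and 0.12 with an estimated correlation), including the transcription factor Tcf7 from 1.98 ± 0.85 to 21.4 ± 4.41, with 0.17 without the first D0 library (range 0.00023 to 0.17). The 24 neural stem genes went both ways (4 higher and 4 lower, 4 and 7 over the list alone, adjusted p = 0.91), with a mean log2 change of 0.03 and a negative median and test. Myeloid markers stood apart in the D0 libraries. All 12 were higher in the second than in the first, by 43.1-fold to 694-fold, as for the macrophage lysozyme Lyz2 at 2370 against 5.58 CPM.

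The same question was asked of day 8. An early neural transcription factor had appeared at a low level. Pax6, a regulator of neural progenitors, rose from 0.099 ± 0.0662 CPM (SD, n = 2) at D0 to 2.86 ± 0.889 (n = 3). Stra6 stood at 125 ± 36.7 and Prom1 at 26.2 ± 0.878, and the endothelial surface protein Emcn rose from 0.182 ± 0.184 to 20.7 ± 6.79, while the endothelial transcription factor Erg fell from 35.4 ± 1.46 to 0.682 ± 0.741. The cartilage collagen Col2a1 fell from 33.6 ± 30 to 0.165 ± 0.15, and S100a4, the fibroblast gene also known as Fsp1, from 187 ± 23.8 to 15.5 ± 6.46.

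Between D8 and D0, 1248 of 17455 genes changed in edgeR's test, 716 higher and 532 lower. Pax6 (ENSMUSG00000027168, chromosome 2, 105509053 to 105543317) had a log2 change of 4.77 (SE 0.68, adjusted p = 0.0014). S100a4 had -3.59 (SE 0.57, adjusted p = 0.0028), Emcn 6.75 (SE 0.87, adjusted p = 0.00091) and Erg -5.67 (SE 1.08, adjusted p = 0.0084). Among the largest changes, Inmt had a ratio of 744 (95% counting interval 206 to 6150) on 2 counts at D0 and the meiotic cohesin Rec8 one of 401 (137 to 1950) on 3 counts. Krt18 was at 30.4 ± 27.8 CPM, and Tnn and Wisp2 had fallen to 0.059 ± 0.0834 and 0.311 ± 0.145. Sox2, a pluripotency and neural stem factor, was at 2.72 ± 1.41 against 0.221 ± 0.276 and did not pass (adjusted p = 0.065, or 0.0091 with a replicate block, range over alternatives 0.0017 to 0.28). Of the 1248 genes, 97.4% had the same sign within batch 1 and 99.7% within batch 2. Batch 2 alone gave 2738 changed genes, with 1050 shared. The count was 792 without the first D0 library, 262 higher and 530 lower, which turns the balance of directions around. It was 622 without the second, 743 without the second D8 library and 758 without the third.

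By list, cartilage and bone markers fell (0 higher and 4 lower of 10, 0 and 6 adjusted over the list alone, fry adjusted p = 3.5e-07, and 0.01 with an estimated correlation). The p53 and arrest genes rose (6 and 0 of 14, 10 and 0 over the list alone, adjusted p = 0.0031, and 0.11 with an estimated correlation), with Cdkn2a at 9.68 ± 2.65 CPM and Perp at 128 ± 62.7. The integrated stress response genes fell (0 and 2 of 14, 1 and 2 over the list alone, adjusted p = 0.0031, and 0.11 with an estimated correlation), as did the mesenchymal transcription factors (1 and 3 of 18, 1 and 5 over the list alone, adjusted p = 0.0063, and 0.11 with an estimated correlation), including Meox1 at 0.404 ± 0.257 against 30.9 ± 0.17. Retinoic acid targets rose (3 and 0 of 11, 7 and 0 over the list alone, adjusted p = 0.0069, and 0.11 with an estimated correlation), with 0.064 without the second D0 library (range 0.00019 to 0.11). Astrocyte genes rose (6 and 0 of 13, 6 and 1 over the list alone, adjusted p = 0.012, and 0.16 with an estimated correlation), with 0.081 and 0.064 without the first and the second D0 library (range 7.6e-05 to 0.16). Endothelial and epithelial markers also passed with fry, and lost the call with an estimated correlation (adjusted p = 0.17 and 0.16). The neural stem genes did not pass as a list (6 and 3 of 24, 9 and 4 over the list alone, adjusted p = 0.063, and 0.039 with a batch term, range 0.00069 to 0.34). Among myeloid markers, Csf1r, Ctss and Itgam were called lower, with 209, 133 and 215 CPM in the second D0 library and 0.833, 0.479 and 0.791 in the first. Without the second D0 library their log2 changes were 0.41, 0.47 and 1.24 (adjusted p = 0.86, 0.86 and 0.64). The calls were also lost without D8 replicate 2 (0.054, 0.055 and 0.094), those of Ctss and Itgam without D8 replicate 3 (0.058 and 0.071), and that of Itgam without D8 replicate 1 (0.07). With voom all 3 were lost (0.39, 0.44 and 0.46), and with a replicate block that of Ctss (0.053). With a replicate block Ctss had 0.053. The ranges were 7.9e-07 to 0.86, 0.00013 to 0.86 and 0.0011 to 0.64.

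Day 12 closes the treated course. More neural stem genes were now higher than at D0. Pax6 was at 3.49 ± 1.07 CPM (SD, n = 3), against 0.099 ± 0.0662 (n = 2) at D0. Among targets of FGF/ERK signalling, the transcription factor Etv1 rose from 7.67 ± 5.88 to 139 ± 13.7, Phlda1 from 16.6 ± 7.25 to 134 ± 3.81 and the feedback inhibitor Spry2 from 33.4 ± 8.01 to 189 ± 44.5. Snap25, part of the machinery of synaptic release, rose from 0.0417 ± 0.0589 to 8.23 ± 1.57, while the neuronal tubulin Tubb3 fell from 13 ± 6.52 to 2.43 ± 0.299. Acta2 and Cnn1 were low at D12, at 193 ± 49.6 and 3.35 ± 0.49.

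Between D12 and D0, 1840 of 17455 genes changed in edgeR's test, 1015 higher and 825 lower. Etv1 (ENSMUSG00000004151, chromosome 12, 39505967 to 39594802) had a log2 change of 4.18 (SE 0.47, adjusted p = 0.00029), Pax6 of 5.06 (SE 0.69, adjusted p = 9e-04) and Snap25 of 7.42 (SE 1.13, adjusted p = 0.0018). Among the largest changes, the ganglioside synthase St8sia1 rose from 0.102 ± 0.114 to 46.6 ± 18.5 CPM and Nppc, which encodes C-type natriuretic peptide, from 0.0807 ± 0.00364 to 38.1 ± 44.3. Wisp2 was lower by a ratio of 3810 (95% counting interval 1300 to 18500) on 3 counts at D12. Sox2, Olig2 and the radial glia gene Fabp7 passed with the first D12 library far above the others. Sox2 was at 12.2 in that library and at 1.52 and 2.8 in the second and the third, Olig2 at 46 beside 2.74 and 5.77, and Fabp7 at 851 beside 118 and 208. Their adjusted p-values were 0.019, 0.0092 and 0.0092. Without the second D0 library they were 0.12 for Sox2, 0.052 for Olig2 and 0.065 for Fabp7, and without the first 0.079 for Olig2 and 0.081 for Fabp7. With voom they were 0.057 for Sox2 and 0.071 for Olig2. Over their alternatives they ranged from 1.4e-05 to 0.12, 1.8e-09 to 0.079 and 1.9e-12 to 0.081. The same sign was found for 97.3% of the 1840 genes within batch 1 and for 99.8% within batch 2, which alone gave 3948 changed genes with 1616 shared. The count was 1037 without the first D0 library, 374 higher and 663 lower, again with the balance turned around. It was 791 without the second, 1091 without the second D12 library and 1000 without the third.

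The FGF/ERK targets rose as a list (10 higher and 1 lower of 15, 11 and 1 adjusted over the list alone, fry adjusted p = 0.0014, and 0.079 with an estimated correlation). The integrated stress response genes fell (0 and 4 of 14, 0 and 5 over the list alone, adjusted p = 0.00018, and 0.017 with an estimated correlation), with Chac1 at 1.33 ± 0.291 CPM against 31.1 ± 10.7. The contractile genes fell (0 and 10 of 16, 0 and 12 over the list alone, adjusted p = 0.001, and 0.059 with an estimated correlation), as did cartilage and bone markers (0 and 4 of 10, 0 and 5 over the list alone, adjusted p = 3.5e-07, and 0.016 with an estimated correlation), with Comp at 0.16 ± 0.0453. The p53 and arrest genes were higher (6 and 0 of 14, 8 and 0 over the list alone, adjusted p = 0.0019, and 0.12 with an estimated correlation), with Perp at 133 ± 47.1. The neural stem genes rose (12 and 1 of 24, 13 and 3 over the list alone, adjusted p = 0.014, and 0.21 with an estimated correlation), with 0.075 and 0.068 without the first and the second D0 library (range 7.9e-07 to 0.21). Neuronal genes rose on balance (2 and 3 of 19, 11 and 3 over the list alone, adjusted p = 0.0076, and 0.2 with an estimated correlation), with 0.068 without the second D0 library (range 0.0092 to 0.2). Myeloid markers were lower in 11 of 12 without the list passing (0 and 12 over the list alone, adjusted p = 0.09), and among D0 libraries they were high in replicate 2. With a batch term the list passed with 0.043, and without D0 replicate 1 it had 1.2e-05 (range 1.8e-06 to 0.33).

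**Figure D2:**
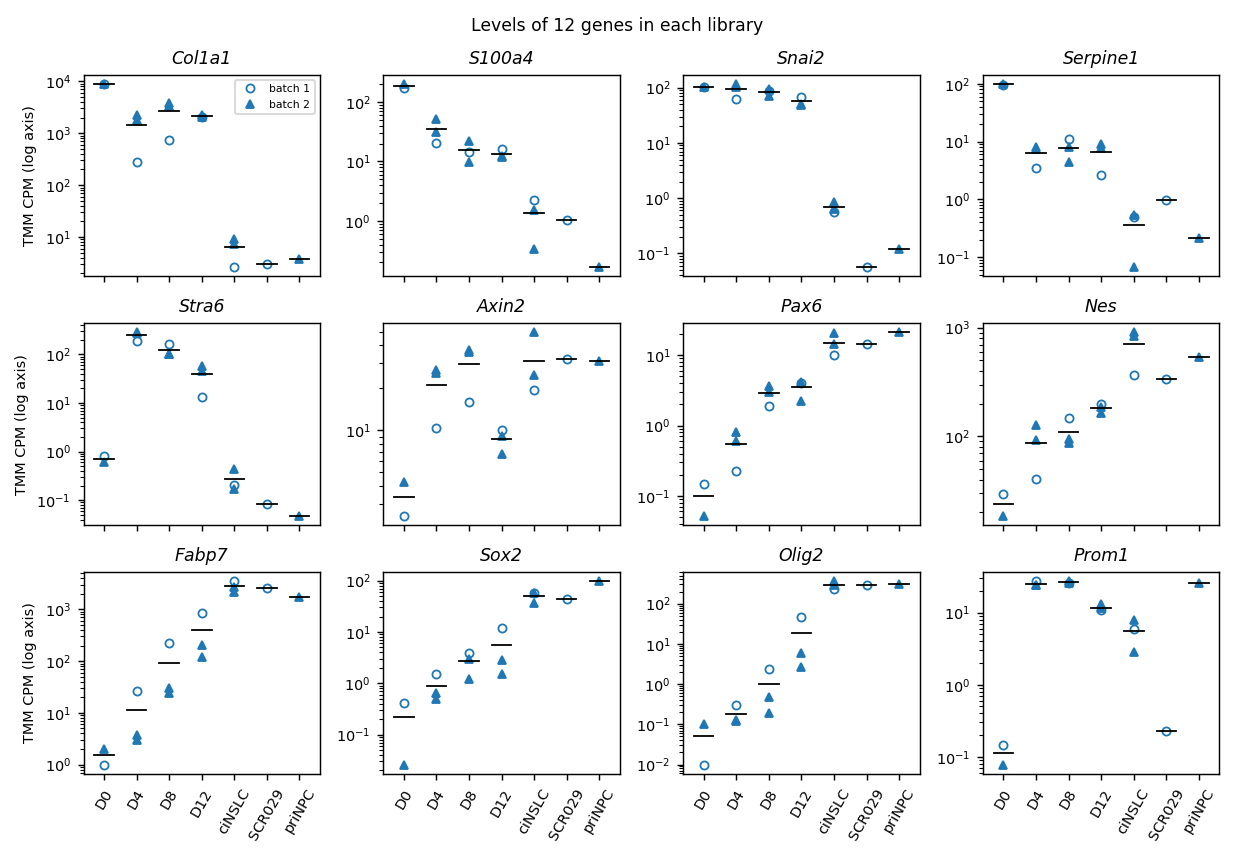
Level of 12 panel and list genes in each library, as TMM-scaled CPM on a log axis; points are libraries (open circles batch 1, filled triangles batch 2), lines are group means, and a library with no counts is drawn at 0.01. Col1a1 stood at 8890 at D0 and 6.45 in ciNSLC, and Fabp7, Sox2 and Olig2 at D12 were highest in the batch 1 library.

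The change from day 4 to day 8 was small beside the spread between libraries. Tagln and Mylk, a structural and a kinase gene of smooth muscle contraction, were higher at D8, at 90.4 ± 53.4 CPM (SD, n = 3) against 11.7 ± 0.188 (n = 3) and at 58.5 ± 27.9 against 8.6 ± 1.39. The muscle actin nucleator Lmod1 was at 13.1 ± 2.61 against 2.33 ± 0.678, the guidance molecule Sema5b at 10.6 ± 4.82 against 0.953 ± 0.443 and the water channel Aqp4 at 5.12 ± 4.65 against 0.218 ± 0.129. Between D8 and D4, 28 genes changed, 28 higher and 0 lower, with 1186 at an unadjusted p under 0.05. DESeq2 gave 254 higher and 34 lower and limma voom 9 and 1. The log2 changes were 2.95 (SE 0.38, adjusted p = 0.018) for Tagln (ENSMUSG00000032085, chromosome 9, 45737711 to 45744141), 2.76 (SE 0.4, adjusted p = 0.021) for Mylk, 2.48 (SE 0.38, adjusted p = 0.022) for Lmod1, 3.47 (SE 0.48, adjusted p = 0.019) for Sema5b and 4.46 (SE 0.75, adjusted p = 0.04) for Aqp4. All 5 lost the call without the first D4 library (adjusted p = 0.089 to 0.17), the second (0.14 to 0.21) or the third (0.15 to 0.28), and over the alternatives Tagln ranged from 2.1e-10 to 0.15 and Aqp4 from 1.5e-07 to 0.28. Without the third D8 library 4 of the 5 lost it (0.059 to 0.068), and without the second Lmod1 did (0.053). Aqp4 also lost it with a replicate block (0.062), and Sema5b, Lmod1 and Aqp4 with voom (0.052, 0.072 and 0.16). No list passed with fry. The contractile genes (2 higher of 16, 6 over the list alone) and the neural stem genes (0 of 24, 7 over the list alone) both had adjusted p = 0.11 (range 1.8e-13 to 0.25 and 8.5e-14 to 0.29). The contractile genes passed without D8 replicate 1 (0.019) and without D8 replicate 3 (0.031). The count was 3 without the first D4 library, 0 without the second, 1 without the third, 67, 13 and 3 without D8 replicates 1, 2 and 3, and 45 with a replicate block. All 28 genes had the same sign within either batch (100% and 100%), and batch 2 alone gave 578 changed genes, 27 of the 28 among them.

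From day 8 to day 12, 3 genes stood out. Meox1, a transcription factor of the paraxial mesoderm, rose from 0.404 ± 0.257 CPM (SD, n = 3) to 27.7 ± 1.21 (n = 3), which is near its level of 30.9 ± 0.17 (n = 2) at D0. Aldh1a3, which makes retinoic acid from retinal, rose from 1.75 ± 0.18 to 87.5 ± 8.33, and the chemokine Ccl11 from 5.29 ± 3.4 to 215 ± 30. Between D12 and D8, 28 genes changed, 16 higher and 12 lower, with 1790 at an unadjusted p under 0.05. The log2 change was 6.12 (SE 0.49, adjusted p = 0.00024) for Meox1 (ENSMUSG00000001493, chromosome 11, 101738824 to 101755688), 5.64 (SE 0.47, adjusted p = 0.00024) for Aldh1a3 (ENSMUSG00000015134, chromosome 7, 73535778 to 73572403) and 5.34 (SE 0.53, adjusted p = 0.0011) for Ccl11 (ENSMUSG00000020676, chromosome 11, 81871325 to 81876457). These 3 kept their call with every library left out in turn, and the other 6 genes named by the rule lost theirs with at least 1 library left out. The latter were Npr3, a natriuretic peptide receptor (1.92 ± 0.863 against 30.2 ± 14.8), Lgals3, Bex1 and Lmod1, all lower, and Sox9 and Egr2, higher. Without the second and the third D12 library, 6 of the 9 named genes lost the call (adjusted p = 0.054 to 0.16 and 0.057 to 0.16), without the second D8 library 5 (0.062 to 0.17), and without D8 replicate 1, D8 replicate 3 or D12 replicate 1 it was 2 each (0.059 to 0.078, 0.067 to 0.095 and 0.066 to 0.069). Lgals3 also lost it with voom (0.077).

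Of the lists, 4 passed from D8 to D12 with fry and 0 with an estimated correlation. Retinoic acid targets fell (0 higher and 0 lower of 11, 0 and 7 adjusted over the list alone, adjusted p = 0.027, and 0.055 with an estimated correlation) and the contractile genes fell (0 and 1 of 16, 0 and 8 over the list alone, adjusted p = 0.038, and 0.094 with an estimated correlation). FGF/ERK targets rose (0 and 0 of 15, 9 and 0 over the list alone, adjusted p = 0.041, and 0.12 with an estimated correlation) and integrated stress response genes fell (0 and 0 of 14, 0 and 2 over the list alone, adjusted p = 0.038, and 0.094 with an estimated correlation). With a replicate block these p-values were 0.05, 0.067, 0.05 and 0.077. Without the first D12 library they were 0.077, 0.1, 0.11 and 0.085, and without the second D8 library 0.062, 0.08, 0.14 and 0.11. Without the third D12 library they were 0.075, 0.095, 0.095 and 0.095. The last 3 lists gave 0.064 each without the second D12 library, and without the third D8 library FGF/ERK targets gave 0.17 and stress response genes 0.092. Over all alternatives the ranges were 2.4e-08 to 0.077, 1.3e-12 to 0.1, 6.5e-08 to 0.17 and 0.0062 to 0.11. The count of changed genes was 58, 8 and 13 without D8 replicates 1, 2 and 3 and 68, 5 and 3 without D12 replicates 1, 2 and 3. It was 124 with a replicate block, 537 with DESeq2 and 122 with voom. All 28 genes had the same sign within either batch, and batch 2 alone gave 1492, with all 28 among them.

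The established lines were compared with the starting fibroblasts. The fibroblast genes were nearly gone. Type I collagen Col1a1 was at 6.45 ± 3.44 CPM (SD, n = 3) against 8890 ± 92.9 (n = 2), the receptor Pdgfrb at 0.157 ± 0.1 against 192 ± 2.67 and the mesenchymal transcription factor Snai2 at 0.682 ± 0.148 against 102 ± 0.534. Among neural stem genes, the transcription factors Sox2, Olig2 and Pax6 were in ciNSLC at 50.2 ± 11.1, 294 ± 65.6 and 14.9 ± 5.14, against 0.221 ± 0.276, 0.0521 ± 0.0737 and 0.099 ± 0.0662. The intermediate filament Nes was at 705 ± 292 against 24 ± 7.64 and Fabp7 at 2800 ± 685 against 1.52 ± 0.73.

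Between ciNSLC and D0, 4925 of 17455 genes changed in edgeR's test, 2048 higher and 2877 lower. No library left out moved the total by more than 1.5 times, but without the first D0 library it was 1205 higher and 2346 lower. Col1a1 (ENSMUSG00000001506, chromosome 11, 94797538 to 94814356) had a log2 change of -10.43 (SE 1.05, adjusted p = 1.7e-05) and Snai2 (ENSMUSG00000022676, chromosome 16, 14705945 to 14709488) of -7.24 (SE 0.34, adjusted p = 1.1e-07). Sox2 (ENSMUSG00000074637, chromosome 3, 34548927 to 34551383) had 7.74 (SE 1.24, adjusted p = 5e-04) and Nes (ENSMUSG00000004891, chromosome 3, 87775000 to 87784373) 4.88 (SE 0.59, adjusted p = 6.4e-05). Among genes without counts at D0, Dab1, an adaptor of reelin signalling, was at 36.5 ± 15.7 CPM and at least 1020-fold higher. Zcchc5 was at least 2850-fold lower, and Rspo2, an amplifier of Wnt signalling, was lower by a ratio of 7760 (95% counting interval 1390 to 306000) on 1 count. Mki67, a marker of cycling cells (426 ± 70 against 488 ± 24.6), Cdkn1a (401 ± 101 against 490 ± 149), Nanog (0.341 ± 0.178 against 0.443 ± 0.0371) and Elk1 (22.4 ± 1.81 against 22.2 ± 0.238) did not pass, with adjusted p = 0.92, 0.56, 0.78 and 0.97. Pou5f1, at 0.0458 ± 0.0465 and 0.146 ± 0.206, was too low to be tested. Within batch 1, 99.2% of the 4925 genes had the same sign and within batch 2, 99.9%, with 6012 changed in batch 2 alone and 4328 shared.

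All 32 lists were tested between ciNSLC and D0, and counts are given as higher and lower members. With an estimated correlation 5 of the 22 lists that passed with fry kept the call, and all 5 had fallen. These were fibroblast matrix and surface genes (0 and 23 of 24, adjusted over the list alone 0 and 24, adjusted p = 2.6e-05, and 0.046 with an estimated correlation), mesenchymal transcription factors (0 and 14 of 18, alone 0 and 15, 1.5e-07, and 0.0028), and contractile genes (0 and 15 of 16, alone 0 and 15, 3.2e-06, and 0.032). The others were integrated stress response genes (0 and 7 of 14, alone 0 and 8, 3.2e-06, and 0.034), and cartilage and bone markers (1 and 7 of 10, alone 1 and 7, 1.5e-07, and 0.046). Lists that rose with fry but lost the call with an estimated correlation were neural stem genes (19 and 3 of 24, alone 21 and 3, 2e-04, and 0.079), astrocyte genes (10 and 0 of 13, alone 10 and 0, 6e-04, and 0.098), neuronal genes (8 and 3 of 19, alone 10 and 3, 0.0015, and 0.14). So did oligodendrocyte lineage genes (7 and 3 of 13, alone 8 and 3, 0.016, and 0.35), FGF/ERK targets (11 and 0 of 15, alone 11 and 0, 0.0011, and 0.16) and Wnt targets (4 and 1 of 12, alone 4 and 1, 0.023, and 0.42). The astrocyte genes included the aldolase Aldoc (548 ± 180 against 8.5 ± 5.91 CPM) and the glutamate transporter Slc1a2 (394 ± 292 against 0.552 ± 0.251). The oligodendrocyte list included Olig1 (845 ± 67.9 against 0.12 ± 0.0516) and, against its direction, the receptor Pdgfra (5.97 ± 1.41 against 224 ± 88.4). Lists that fell with fry and lost the call with an estimated correlation were TGF-beta targets (0 and 11 of 12, alone 0 and 11, 5.1e-05, and 0.065) and BMP targets (0 and 5 of 12, alone 1 and 7, 0.00029, and 0.18), with retinoic acid targets (0 and 4 of 11, alone 1 and 5, 0.0018, and 0.29), Hox genes (7 and 17 of 36, alone 7 and 19, 0.003, and 0.43). Hedgehog targets (1 and 4 of 10, alone 2 and 5, 0.045, and 0.62) and hypoxia targets (0 and 8 of 20, alone 0 and 9, 0.025, and 0.62) did too. Further such lists were germline genes (0 and 1 of 5, alone 1 and 2, 0.012, and 0.62), autophagy genes (0 and 0 of 13, alone 0 and 0, 0.021, and 0.67). The last were myeloid markers (0 and 12 of 12, alone 0 and 12, 0.023, and 0.45), endothelial markers (0 and 2 of 7, alone 0 and 2, 0.0043, and 0.45) and adipocyte markers (0 and 2 of 5, alone 0 and 2, 0.0016, and 0.24). With a preset correlation the oligodendrocyte, Hedgehog, Wnt, germline, autophagy, endothelial and adipocyte lists lost the call (adjusted p = 0.11, 0.17, 0.06, 0.53, 0.38, 0.34 and 0.078), and the other lists that passed with fry kept it. The lists that did not pass were neural crest genes (2 and 2 of 11, alone 2 and 2, 0.69), pluripotency genes (1 and 1 of 5, alone 1 and 1, 0.17), forebrain genes (2 and 3 of 11, alone 2 and 3, 0.17), midbrain and hindbrain genes (3 and 4 of 11, alone 3 and 4, 0.18) and proliferation genes (0 and 0 of 24, alone 0 and 0, 0.57). Nor did p53 and arrest genes (1 and 1 of 14, alone 1 and 1, 0.4), cholesterol synthesis genes (0 and 1 of 19, alone 0 and 1, 0.87), interferon-stimulated genes (0 and 5 of 16, alone 0 and 7, 0.062), epithelial markers (0 and 1 of 7, alone 0 and 1, 0.21) and skeletal muscle markers (2 and 2 of 9, alone 2 and 2, 0.38). Median and test differed in sign for neural crest, forebrain and epithelial lists, and mean and test for neural crest, pluripotency and skeletal muscle lists. Calls lost with a library left out were those of the oligodendrocyte list (0.33 and 0.093 without the first and the second D0 library, range 0.0014 to 0.35), Wnt targets (0.48 without the first D0 and 0.063 without the third ciNSLC library, range 0.015 to 0.48) and myeloid markers (0.056 without the first ciNSLC library, range 3.1e-06 to 0.45). Hedgehog targets lost it without the first or second D0 library (0.096 and 0.072) and without the first or second ciNSLC library (0.16 and 0.12, range 0.018 to 0.62). Hypoxia targets lost it without the first D0 library (0.15) and without any of the 3 ciNSLC libraries (0.079, 0.063 and 0.053, range 0.015 to 0.62), and autophagy genes without D0 replicate 2 or ciNSLC replicates 2 and 3 (0.093, 0.081 and 0.06, range 0.014 to 0.67). Calls gained were those of pluripotency genes and interferon-stimulated genes without D0 replicate 1 (0.04 and 0.045), forebrain genes without ciNSLC replicate 3 (0.03) and skeletal muscle markers without D0 replicate 2 (0.038). The interferon-stimulated genes also passed with a replicate block (0.019), with a batch term (0.0085) and with a preset correlation (0.049). The ranges of these 4 were 0.04 to 0.89, 0.0085 to 0.66, 0.03 to 0.9 and 0.038 to 0.99.

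The lines were then set against day 12. Mesenchymal regulators fell, with Snai2 from 56.3 ± 10.8 CPM (SD, n = 3) to 0.682 ± 0.148 (n = 3), Foxc2 from 7.23 ± 0.363 to 0.0452 ± 0.0445 and Meox1 from 27.7 ± 1.21 to 0.287 ± 0.103. Among neural stem genes, the transcription factor Lhx2 rose from 2.53 ± 1.25 to 42.8 ± 6.2, the RNA-binding protein Msi1 from 7.67 ± 3 to 50 ± 6.65 and the Notch ligand Dll1 from 0.433 ± 0.237 to 13.7 ± 2.82. Of the p53 response, Mdm2 fell from 914 ± 407 to 117 ± 30.5 and Cdkn1a from 995 ± 103 to 401 ± 101, and the mitotic genes Top2a and Bub1b rose from 88 ± 62.8 to 408 ± 76.3 and from 9.51 ± 6.15 to 36.8 ± 12.4. The endothelial proteoglycan Esm1 and the proteases Mmp3 and Mmp9, present at D12 at 86.2 ± 38.5, 25.5 ± 12.9 and 17.4 ± 12.2, were at least 2780-fold, 805-fold and 550-fold lower.

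Between ciNSLC and D12, 4808 of 17455 genes changed in edgeR's test, 1926 higher and 2882 lower. The log2 change was -6.38 (SE 0.32, adjusted p = 2.2e-07) for Snai2, 4.08 (SE 0.4, adjusted p = 2e-05) for Lhx2, -1.31 (SE 0.29, adjusted p = 0.0052) for Cdkn1a and 2.21 (SE 0.52, adjusted p = 0.0071) for Top2a. The mesenchymal transcription factors fell as a list (0 and 14 of 18, 0 and 14 adjusted over the list alone, fry adjusted p = 8.4e-07, and 0.0066 with an estimated correlation), the only list of the 18 that passed with fry to keep the call with an estimated correlation. The neural stem genes rose (18 and 2 of 24, 19 and 2 over the list alone, adjusted p = 0.00027, and 0.14 with an estimated correlation), as did proliferation genes (12 and 0 of 24, 19 and 0 over the list alone, adjusted p = 0.01, and 0.38 with an estimated correlation). The p53 and arrest genes fell (0 and 9 of 14, 0 and 12 over the list alone, adjusted p = 0.00027, and 0.2 with an estimated correlation), as did retinoic acid targets (0 and 6 of 11, 1 and 6 over the list alone, adjusted p = 0.00051, and 0.2 with an estimated correlation). Hedgehog targets fell (2 and 6 of 10, 2 and 6 over the list alone, adjusted p = 0.0099, and 0.43 with an estimated correlation), with 0.055 without the first ciNSLC library (range 0.0055 to 0.43). Within them Foxf2 was at least 88.1-fold lower, while the receptor gene Gas1 rose from 30.4 ± 19.9 to 128 ± 74.9. The count was 3001 (980 higher and 2021 lower) and 3009 (982 and 2027) without the second and the third D12 library. The same sign was found for 98.9% of the genes within batch 1 and 100% within batch 2, which alone gave 8148 changed genes, 4649 of them shared.

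**Figure D3:**
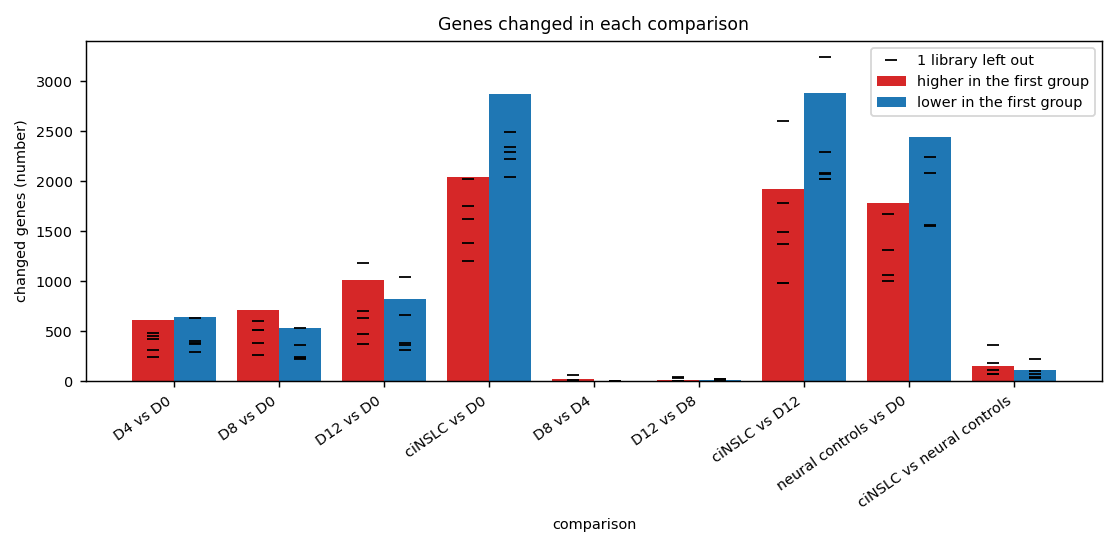
Number of genes called higher (red) and lower (blue) in the first group of each of the 9 comparisons; short black lines give the counts with 1 library left out. From D4 to D8 and from D8 to D12 the counts were 28 each, beside 4925 between ciNSLC and D0 and 4808 between ciNSLC and D12.

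The neural controls against D0 show what cortical progenitors differ in from the fibroblasts. Neural stem genes were high, with Sox2 at 71 ± 37.6 CPM (SD, n = 2), Pax6 at 17.7 ± 4.66 and Nes at 434 ± 141. So were forebrain genes, with Otx2 at 37.1 ± 6.92 (42 in SCR029 and 32.3 in priNPC) and at least 1060-fold higher than at D0. Fibroblast genes were low, with Col1a1 at 3.41 ± 0.57 against 8890 ± 92.9 (n = 2). Hox genes, which mark trunk and limb position, were lower in 28 of 36, as for Hoxb5 and Hoxc5, with no counts in either control and at least 57.1-fold and 125-fold lower. Hoxd13 was lower by a ratio of 1950 (95% counting interval 666 to 9440).

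Between the controls and D0, 4222 of 17636 genes changed in edgeR's test, 1780 higher and 2442 lower. Forebrain genes rose as a list (6 and 1 of 12, 7 and 1 adjusted over the list alone, fry adjusted p = 8.4e-06, and 0.02 with an estimated correlation). Hox genes fell (0 and 28 of 36, 0 and 29 over the list alone, adjusted p = 3.8e-06, and 0.014 with an estimated correlation). Neural stem genes rose (21 and 1 of 24, 22 and 1 over the list alone, adjusted p = 0.00013, and 0.046 with an estimated correlation), and fibroblast genes fell (0 and 23 of 24, 0 and 23 over the list alone, adjusted p = 1.8e-05, and 0.023 with an estimated correlation). The neural crest and oligodendrocyte factor Sox10 was called higher on a mean of 8.34 ± 11.8, with 0 in SCR029 and 16.7 in priNPC. Against SCR029 alone its log2 change was -3.58 (adjusted p = 0.38), and the call was lost without D0 replicate 1 or 2 (0.11 and 0.095) and with voom (0.4, range 4.8e-05 to 0.4). Within batch 1 99% of the 4222 genes had the same sign and within batch 2 99.7%, with 5781 changed in batch 2 alone and 3663 shared. The count was 2628 (1063 higher and 1565 lower) without the second D0 library and 3088 (1002 and 2086) without the first. Against priNPC alone it was 3229, with slightly more higher than lower genes (1672 and 1557).

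Whether the lines moved toward the controls was asked by overlap. Of 1927 genes higher in ciNSLC than at D0 in the fit of 16 libraries and 1780 higher in the controls, 1335 were the same, and of 2656 and 2442 lower genes 1883 were the same. In opposite directions 8 genes were called. Independent lists of these sizes would share 194 and 368 genes. Both comparisons use the same D0 libraries, which ties their changes together. In 20 simulations with unchanged groups the shared calls averaged 0 in each direction, with a highest count of 1 for higher and 0 for lower genes. At most 0.1 genes per direction were called there on average, so this count does not measure how many shared calls the common D0 libraries add. The covariance of the log2 changes was 6.04, beside 0.39 in the simulations. Their Pearson correlation across genes was 0.89 beside 0.54, and the share with the same sign 80.7% beside 68.7%. Part of the excess may come from the shared controls. With ciNSLC set against the first D0 library and the controls against the second, 615 higher and 1106 lower genes were shared, where independent lists would share 63 and 193, and 19 were called in opposite directions. The covariance was 5.07 and the correlation 0.68. With the 2 D0 libraries exchanged 670 and 1111 were shared, with 59 and 169 for independent lists, 13 opposite calls, a covariance of 5.2 and a correlation of 0.71. Without the first D0 library 732 higher genes were shared, and without the second 826 higher and 1187 lower.

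The last comparison set the lines against the neural controls. The panel of neural stem genes was at like levels. Sox2 was at 50.2 ± 11.1 CPM (SD, n = 3) against 71 ± 37.6 (n = 2), Pax6 at 14.9 ± 5.14 against 17.7 ± 4.66, Olig2 at 294 ± 65.6 against 299 ± 8.55 and Nes at 705 ± 292 against 434 ± 141, none passing the test. Regional genes differed. Otx2 was lower in ciNSLC by a ratio of 1160 (95% counting interval 398 to 5640) on 3 counts, and Zic1, a transcription factor of the dorsal neural tube, went from 43.7 ± 16.3 in the controls to 0.309 ± 0.235. Hox genes were higher, with Hoxb5 at 8.38 ± 1.78, Hoxb4 at 8.06 ± 0.038 and Hoxb3 at 2.21 ± 0.931, at least 215-fold, 207-fold and 61.9-fold over controls without counts. Hypoxia targets were lower, with the oxygen sensor Egln3 at 12 ± 2.55 against 73.5 ± 3.32 and Ankrd37 at 0.256 ± 0.0866 against 5.16 ± 2.87.

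Between ciNSLC and the controls, 270 of 17636 genes changed in edgeR's test, 155 higher and 115 lower. The glutathione transferase Gstt3 rose with a log2 change of 7.14 (SE 0.57, adjusted p = 4.2e-05) to 39.3 ± 8.01 CPM. The peptidase Mme, also known as neprilysin, rose with 5.76 (SE 1.06, adjusted p = 0.017) to 128 ± 13.3, the gene listed as Ccrl1 (ENSMUSG00000079355) with 8.82 (SE 0.96, adjusted p = 0.00042), and the reductase Cybrd1 with 5.73 (SE 0.89, adjusted p = 0.0059). Otx2 (ENSMUSG00000021848, chromosome 14, 49277354 to 49287319, adjusted p = 6.5e-05) and Zic1 (log2 change -7.04, SE 0.61, adjusted p = 6.5e-05) fell, and Hoxb5 (ENSMUSG00000038700, chromosome 11, 96163909 to 96167434, adjusted p = 5.2e-06) rose. For Sox2, Pax6, Olig2 and Nes the log2 differences were -0.5 (SE 0.81), -0.24 (SE 0.48), -0.02 (SE 0.99) and 0.7 (SE 0.48), which leaves differences of over 2-fold open. Of the lists 4 passed, and all 4 kept the call with an estimated correlation. Forebrain genes fell (0 and 3 of 12, 0 and 7 adjusted over the list alone, fry adjusted p = 6.9e-06, and 3e-04 with an estimated correlation) and Hox genes rose (14 and 0 of 36, 20 and 0 over the list alone, adjusted p = 0.00027, and 0.004 with an estimated correlation). Hypoxia targets fell (0 and 9 of 20, 0 and 16 over the list alone, adjusted p = 0.0017, and 0.016 with an estimated correlation) and integrated stress response genes fell (0 and 2 of 14, 0 and 6 over the list alone, adjusted p = 0.0053, and 0.029 with an estimated correlation), with Chac1 at 0.434 ± 0.122 against 5.31 ± 4.06 and the receptor Vldlr at 21.9 ± 12.4 against 143 ± 47.5. All 270 genes had the same sign within either batch, with 2148 (870 higher and 1278 lower) changed in batch 2 alone and 229 shared. The count was 109 (77 higher and 32 lower) and 113 (72 and 41) without the first and the second ciNSLC library. The balance of directions depended on the control, with 363 higher and 100 lower of 463 against SCR029 alone, and 116 higher and 220 lower of 336 against priNPC alone.

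**Figure D4:**
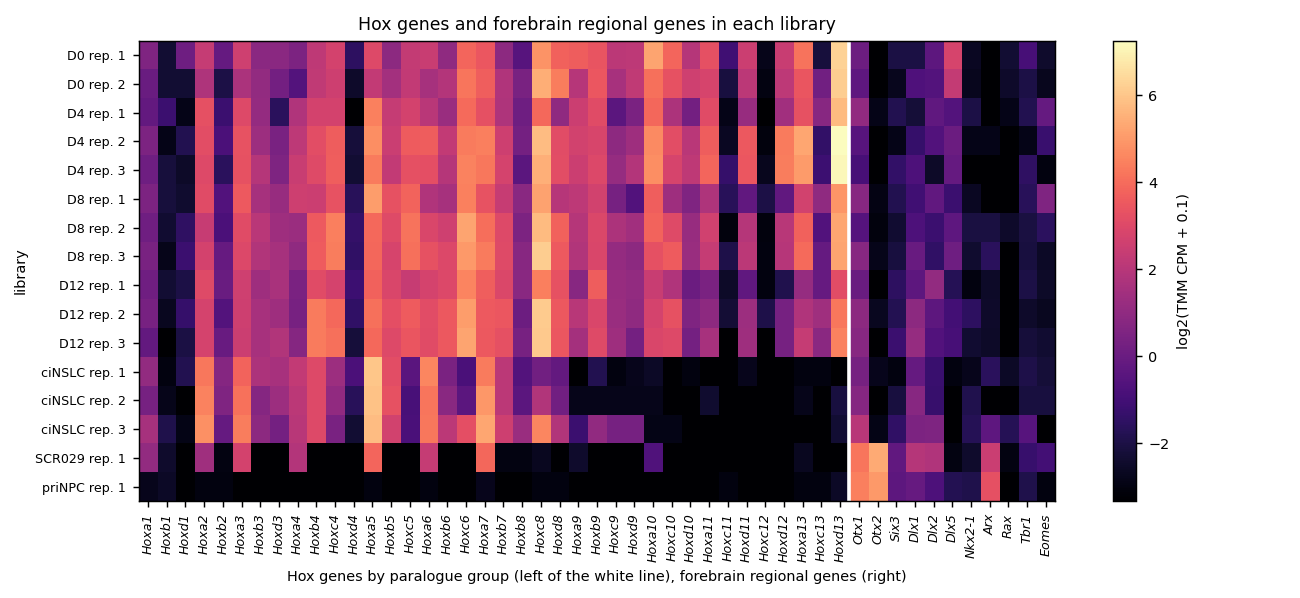
Level of each Hox gene, ordered by paralogue group, and of each forebrain regional gene that is not also in the neural stem list, in every library, as log2 of TMM-scaled CPM plus 0.1; the white line parts both sets, columns are genes and each line of the map is a library. Otx2 was bright in SCR029 and priNPC and dark in ciNSLC (37.1 CPM against 0.0268), while Hoxb5 showed the reverse.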

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

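Chosen after the data were seen were the tests with batch 2 libraries only, without the mitochondrial rRNA genes, without 4 doubted libraries, and with D0 divided; all other alternatives were planned. Named genes kept direction and side of the threshold in 6964 of 7893 comparisons with an alternative, lost the call in 860, gained one in 64 and reversed in 5. Lists did so in 2570, 211, 97 and 2 of 2880. DESeq2 size factors left 806 of 808 genes and 286 of 288 lists the same. Voom cost 109 of 808 genes their call, and leaving out libraries 728 of 4055. Of named genes called, 36 of 81 were called in every such fit between D4 and D0, 38 of 88 for D8, 40 of 105 for D12, 105 of 133 for ciNSLC, 0 of 5 between D8 and D4, 3 of 9 between D12 and D8, 107 of 140 between ciNSLC and D12, 91 of 129 between controls and D0 and 18 of 27 between ciNSLC and controls. Upper-quartile scaling moved the median log2 change of all genes from 0.02 to 0.12 between D4 and D0.

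The number of genes called depended on the test. Between D4 and D0 it was 1260, and 2262 with DESeq2, 2328 with a batch term, 548 with only the groups compared, 2626 in batch 2 and 2273 without the doubted libraries, with 609 to 885 when 1 library was left out. In the same order it was 1248, 2298, 2186, 550, 2738 and 2891 between D8 and D0 (622 to 969), and 1840, 2935, 2867, 898, 3948 and 4204 between D12 and D0 (791 to 2225). Between D8 and D4 it was 28, 288, 102, 1, 578 and 488 (0 to 67), with 43 without a filter, 10 with voom and 45 with a replicate block. Between D12 and D8 it was 28, 537, 279, 6, 1492 and 1131 (3 to 68), with 67, 122 and 124 in those further fits. Between ciNSLC and D12 it was 4808, and 8148 in batch 2 and 8588 without the doubted libraries (3001 to 5845). Between controls and D0 it was 4222, and 1498 with only the groups compared (2628 to 3088 with a D0 library left out). Between ciNSLC and controls it was 270, and 995 with DESeq2, 648 with a batch term and 23 with only the groups compared. It was 463 against SCR029 alone, 2148 in batch 2 and 821 without the doubted libraries. With a ciNSLC library left out it was 109 to 254. Fits on fewer libraries estimate the spread from fewer residuals. At D4, D8 and D12, replicates 2 and 3 of batch 2 had a rho of 0.991, 0.987 and 0.994 with each other. With replicate 1 of batch 1 they had 0.942 to 0.949. Without a batch term the spread at these days thus takes in the difference between batches. In ciNSLC the pair within batch 2 had 0.966 and the pairs across batches 0.983 and 0.964. How far this sets the counts was not tested.

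Of 12, 13, 11, 22, 18 and 23 lists called against D0 at D4, D8, D12 and in ciNSLC, between ciNSLC and D12, and between controls and D0, camera with an estimated correlation called 1, 1, 2, 5, 1 and 8. Unlike fry it sets a list against all other genes, with the correlation between members estimated from the data. Between D8 and D0 6 to 14 were called with a library left out. Between D8 and D4 0 were called, and 8 with a preset correlation (0 to 2 with a library left out). Between D12 and D8 4 were called, 0 with an estimated correlation, 13 with a preset one, 7 with a batch term and 0 with a replicate block (0 to 7). Between ciNSLC and controls 4 were called, 9 with a preset correlation and 7 against SCR029 alone. Genes shared by ciNSLC and controls against D0 numbered 732 to 1274 higher (1335 in all libraries) and 1187 to 1761 lower (1883), and with D0 divided 615 and 670 higher and 1106 and 1111 lower.

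Direction reversed in 7 cases. Sox10 between controls and D0 had -3.58 against SCR029 alone, where it had no counts, and the oligodendrocyte list between ciNSLC and controls had adjusted p = 0.042 there (0.97 otherwise). The others followed from leaving out D0 replicate 2, which held the myeloid signal: Csf1r at D4 (-5.82 to 2.14 over libraries left out) and the myeloid list at D4 (adjusted p = 0.011, with 0.00027 to 0.52), and Csf1r (-7.55 to 0.41), Ctss (-7.63 to 0.47) and Itgam (-6.83 to 1.24) at D8.

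Over the 2000 most variable genes and on log2(FPKM + 1), rho of ciNSLC was 0.759 and 0.927 with SCR029, 0.816 and 0.932 with priNPC, 0.377 and 0.836 with D12, 0.229 and 0.823 with D8, 0.072 and 0.804 with D4, and 0.064 and 0.792 with D0. Between D0 and D4 it was 0.685 over the variable genes. Depth limits genes under 0.054 to 0.102 CPM, the level of 3 counts per library; libraries without rRNA held 14.5 to 34.6 M counts.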

Other observations

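All tests of the 3 patterns weighed in this part were chosen after the results were seen, while the counts over other splits of the libraries were planned. The genes of the next 2 paragraphs were also chosen after their values were seen. Among 16 imprinted genes, which are expressed from 1 parental copy, 13 were called lower and 1 higher in ciNSLC than at D0, and 10 lower and 1 higher in the neural controls. The growth factor Igf2 was at 7140 ± 6630 CPM (SD, n = 2) at D0 and 8.08 ± 4.28 (n = 3) in ciNSLC, and the noncoding RNA H19 at 1190 ± 22.2 and 4.14 ± 2.17. By D12 only 2 of the 16 were called lower, with Igf2 at 4630 ± 322. Grb10 was at 20 in D0 replicate 1 and 1020 in D0 replicate 2.

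The Hox genes parted by position along the cluster. In ciNSLC against D0, the 22 genes of paralogue groups 1 to 8 held 7 higher and 3 lower, while all 14 of groups 9 to 13 were lower. Hoxd13, which patterns the distal limb, went from 75.4 ± 4.06 to 0.0784 ± 0.0697 CPM, and Hoxa5, of the neck and thorax, from 6.38 ± 2.2 to 59.5 ± 4.03. Already at D4 and D8, 4 of the 22 were higher. Hoxa5 was at 14.5 in SCR029 and 0.0239 in priNPC. The Hedgehog target Gli1 differed by batch in treated cells, with 1.58, 2.47 and 8.87 in replicate 1 of D4, D8 and D12 and 29.8 to 51.1 in replicates 2 and 3. The ciNSLC libraries also differed from each other. The Y-linked genes Ddx3y and Kdm5d were at 0.372 and 0.86 in replicate 1, 0.623 and 0.979 in replicate 2, and 19.3 and 29.5 in replicate 3, beside 60 and 28.6 in D0 replicate 1 and 17.7 and 12.9 in D0 replicate 2. Xist, expressed from the inactive X chromosome of female cells, was at 4 and 364 in the D0 libraries, 260 to 794 in the treated ones and 498, 721 and 129 in ciNSLC. The D0 libraries thus differ in sex make-up. By these genes D0 replicate 1 also differs from the treated cells of its batch. In replicate 1 of D4, D8 and D12, Xist was at 357, 332 and 260 and Ddx3y at 15.9, 17.2 and 18.2. Changes against D0 may thus in part reflect different embryos, which was not tested. The labels do not say which embryos gave the lines. The ventral neural tube factor Nkx6-1 was at 16.8, 24.8 and 0.0339 in ciNSLC replicates 1, 2 and 3.

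Other splits of the libraries were counted for the comparisons of 3 against 3. The real grouping gave 28 changed genes between D8 and D4, 28 between D12 and D8 and 4808 between ciNSLC and D12, and the highest of the other splits gave 0 in each. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

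At D12, neural stem genes were higher in replicate 1 than in replicates 2 and 3, by 1.57 on the log2 scale on average, with 22 of 24 higher. Reads of another library mixed into it would bring all abundant transcripts of that donor. As the whole cause such mixing is argued against for 2 donors. For ciNSLC replicate 1, counting limits of Glycam1, Ednrb and Sdk2 allow a share of at most 4.76%, which gives the list a difference of 0.79, with an excess of 0.78 (95% interval over 24 genes 0.39 to 1.16) left. For SCR029, Gpr37l1, Kcnj16 and 2810459M11Rik allow 0.767%, 0.885% and 2.96%, of which the last gives 0.66 and leaves 0.9 (0.39 to 1.42). Other donor genes stood higher. Over 20 donor genes far lower in the other D12 libraries, replicate 1 exceeded those by a median of 12.6% of the ciNSLC replicate 1 level. Over 23 such genes of SCR029 it was 13.9%. The upper quartiles were 2.61 and 3.39 times the lower ones, where mixing alone was predicted to give under 2 times. A smaller part from such reads, and cells of a culture not sequenced here, were not excluded. A shift shared by batch 1 is also argued against as the whole cause, since the difference between replicate 1 and the others was 0.37 at D4, 0.51 at D8 and 0.01 in ciNSLC (10 of 24 higher), at most 32.3% of that at D12. The excess at D12 over D8, the least of the 3, was 1.06 (95% interval over 24 genes 0.62 to 1.5). The intervals of this paragraph, also those for mixing, take the genes of 1 list as independent, which they are not. They cover no variation between libraries or cultures, and D12 replicate 1 is a single library. A batch effect on D12 alone cannot be told apart from a culture that was further along by day 12, which was not tested. The reason is that replicate 1 is the only D12 library of its batch. Its sample description also carries another prefix than those of replicate 1 of D0, D4 and D8, and the meaning is not given.

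The Hox genes called higher in ciNSLC than in the neural controls were set against the starting cells. Fibroblasts left in the ciNSLC cultures are argued against, since the median level of these 14 genes was 123% of D0 (range 10.3% to 550%) while that of 24 fibroblast genes was 0.468%. The fibroblast Hox pattern was not kept as a whole, since all 14 genes of paralogue groups 9 to 13 were lower in ciNSLC than at D0 (median log2 change -8.04). The 14 genes called higher than in the controls are all of groups 1 to 8. Whether the pattern of these genes was kept is not decided. Over them rho between D0 and ciNSLC means was 0.262, between the 0.2 and 0.5 that would have decided. For these genes it stays a candidate explanation. Others that stay open are the retinoic acid in the treatment and the cortical origin of the controls. These were not tested, since no treated culture was left without retinoic acid and no control comes from a more caudal region.

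In D0 replicate 2 the 12 myeloid markers were all at least 5 times higher than in replicate 1 (12 of 12, from 43.1 to 694 times), with Lyz2 at 2370 CPM, Csf1r at 209 and the leukocyte phosphatase Ptprc at 54.2. A shift shared by batch 2 is argued against, since the largest median log2 difference between batches at D4, D8 or D12, 1.24, was 15.9% of the 7.8 at D0. Macrophages in that culture may be the source, a hypothesis that the marker levels bear out but that was formed on the same data. The labels name no sort that would remove such cells. The decrease of Csf1r called at D4 and D8 rests on this library, as without it the log2 change was 2.14 and 0.41. In ciNSLC against D0 the myeloid list kept its call without it (adjusted p = 0.0023, range over alternatives 3.1e-06 to 0.45).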
